A study of Danio rerio with 58 samples.

How the data were processed

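The study measured messenger RNA in pools of zebrafish embryos with 2-colour Agilent oligonucleotide microarrays. The 58 samples are the single channels of 29 arrays, each hybridised with RNA of embryos without maternal and zygotic pou5f3 (MZ) and of wild-type embryos (WT), 1 in Cy3 and 1 in Cy5. The dye of each sample and the file of each array came from the labels, and samples were grouped by the genotype and stage in the labels into 20 groups. RNA was taken from pooled embryos with a column kit and checked for integrity, per the labels' protocols, and the series' design text calls the replicates biological.

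The authors deposited each array's scanner output, extracted with Agilent Feature Extraction 9.5.3.1, per the file headers, which name the zebrafish build danRer2 for the probe positions. These files hold the mean spot intensity and the median local background intensity of both channels on a linear scale, not normalized, per the file headers. A value table of 58 columns and 21539 lines was deposited by the authors as well. Per the series' design text the channels were split and quantile normalized in a commercial package. The column medians of these deposited intensity values lay between 39.46 and 39.51. Their log2 correlated with the log2 scanner signal of the same sample at r of 0.892 to 0.995 across probes, over all columns, so the values are single-channel levels on a linear scale. Which unit or constant they were scaled to stayed unknown. No column was centred on genes, and no ratio direction applies to them.

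The mean intensities were corrected for background with normexp (offset 50), and the log2 ratios were normalized within each array by loess and between arrays with the Aquantile method, in limma 3.58.1 under R 4.3.3 (statmod 1.5.0). Control spots carried no weight in loess and were left out afterwards, as were spots the scanner software marked as outliers, and the 2 spots of each probe were averaged. Of the 21495 probes, 7342 were named by an accession found in the reference gene table, 588 by a current symbol and 2337 by an older one; 10 matched several genes and 11218 kept the name in the file. A gene took the value of its brightest probe. Genes were tested if a probe was well above background in every replicate of at least 1 group, which left 12644 genes. Only probe positions were taken from the array design, and no exon or untranslated region was assigned.

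MZ and WT were compared with limma on the within-array log2 ratios, with 1 coefficient per stage and 1 for the dye, and Benjamini-Hochberg adjustment. A gene counted as different at an adjusted p under 0.05. The same fit gave the change of the MZ-WT difference at 4, 4.7 and 8 hpf against 2.5 hpf. Single-channel log2 values gave the comparison of 0, 4 and 8 hpf with 2.5 hpf within each genotype. MZ was in Cy5 on every array at 1, 2.5, 3, 4, 4.7, 7 and 8 hpf, so with all arrays the dye coefficient rested on 0, 5 and 6 hpf. Without 6 hpf replicate 3, MZ was in Cy3 on every 6 hpf array, and the coefficient rested on 0 and 5 hpf only. The values of single genes and gene lists come from that fit. Estimated from 0 hpf and from 5 hpf alone, the dye coefficient correlated at r of -0.02 across genes. The paired channels of an array are the pairing of MZ with WT. Between 4 and 2.5 hpf in WT, samples of the same number deviated together from their group means (r = 0.196, 0.125 and 0.217 across genes). Replicate 2 there correlated more with a sample of another number (r = 0.22). In the other 5 comparisons between stages at least 1 of the 3 correlations was under 0.1. Whether the numbers pair samples between stages therefore stays open.

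The array labelled 6 hpf replicate 3 ran against the other arrays from 1 to 8 hpf, as given with the results. Counts are therefore given for all 29 arrays as labelled and for the 28 arrays without it, and the values of single genes and gene lists come from the 28 arrays, a choice made after the data were examined. Counts under the other alternatives start from all 29 arrays unless 28 or 25 are named. With its labels kept, Cy5 exceeded Cy3 for pou5f3 on every 6 hpf array, so this array shifts the dye coefficient shared by all stages. That coefficient passed the test for 773 genes with 29 arrays and 70 with 28. The MZ-WT counts with 29 arrays can thus carry part of the 6 hpf difference at other stages. A further fit to 25 arrays also left out the 3 arrays labelled 0 hpf. A probe not well above background on every array of a group has only a bound there. Such a fold is written as "at least", from the mean of the brighter group over all its replicates against the mean, per array, of the higher of the dim probe's own signal and the lowest signal well above background, after the same normalization. It takes no dye coefficient, so it is open to dye bias and can exceed the fitted fold.

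Fixed before the data were examined were the comparisons, 23 gene lists, the alternatives and the rule for named genes. That rule takes pou5f3 in every comparison. For MZ against WT at 4, 6 and 8 hpf it takes the 10 largest changes each way among named genes that passed the test with 1 sign on all arrays, at the other stages 3 each way, and for the comparisons between stages 5 each way. From each list it takes up to 4 members with the smallest adjusted p at 4, 6 and 8 hpf, and all members of a list of up to 6 measured genes. The text names part of the genes this rule gives, chiefly those that kept their call when any single array was left out. The lists were SoxB1 factors, blastula transcription factors, ventral and BMP genes, dorsal organizer genes, Nodal and mesendoderm genes, FGF genes, WNT genes, endoderm genes, yolk syncytial layer genes, enveloping layer genes, neural patterning genes, neuronal differentiation genes, retinoic acid genes, maternal and oocyte genes, cell cycle genes, p53 response and cell death genes, heat shock and stress genes, cell movement and adhesion genes, ovarian somatic and blood markers, housekeeping genes, ribosomal protein genes, and miR-430 processing and zygotic clearance genes. With the target gene they make 23. The 22 others were tested with camera (preset correlation 0.01) at 4, 6 and 8 hpf, adjusted over the 66 tests, with an estimated correlation and fry as alternatives.

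The apparent age of a channel is the point of the averaged WT time course from 1 to 8 hpf, interpolated between stages and without the array itself, with the smallest summed absolute log2 difference from the channel. Recovery was tested on simulated log2 ratios of 12644 genes. A shift of 1 was recovered for 68.7% of the changed genes at 4 hpf, 82.1% at 6 hpf and 71.6% at 8 hpf. For a shift of 0.5 the shares were 22.4%, 40.3% and 26.9%. The simulated noise was independent between genes and arrays, with each gene's residual SD from the fit to 29 arrays. These shares hold for 3 arrays per stage, with both dye orders at 6 hpf, and not for the 2 arrays left there. The alternatives were quantile normalization, Agilent's processed signals, no background subtraction, no filter, the mean of a gene's probes, no dye coefficient, the deposited values, slide as a random block, array weights, channels without their pairing, the arrays of a stage alone, and each array left out in turn. Each of the 9 slides also stands for 1 scan. The arrays of 2.5, 4 and 8 hpf lay on separate slides, so that slide and stage cannot be told apart between these stages, whereas MZ and WT shared every slide.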

Results

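Zebrafish embryos that lack both the egg-supplied and the embryo's own pou5f3 product (MZ) were compared with wild-type embryos (WT) over the first 8 hours of development. The gene pou5f3, also listed as pou5f1 and pou2, encodes a POU-domain transcription factor that mothers store in the egg and that the blastula expresses widely. The labels give 10 stages, at 0, 1, 2.5, 3, 4, 4.7, 5, 6, 7 and 8 hours post fertilization (hpf), which run from the egg through cleavage and blastula into gastrulation. The 0 hpf samples carry "ovary" as their stage and whole embryo as their source. Of the 20 groups, 18 held 3 samples and the 2 groups at 1 hpf held 2. Each sample was RNA of pooled embryos in 1 channel of a 2-colour array, and MZ and WT of the same stage and replicate number shared an array, so the 58 samples came from 29 arrays. Between 35.4% and 62.0% of the probes were well above background in the Cy3 channels and between 58.1% and 69.7% in the Cy5 channels, and the number of arrays limits the precision. The comparison of MZ with WT at each stage asks which transcripts differ without Pou5f3, and the comparison of later stages with 2.5 hpf asks which transcripts change as the embryo's own genome is activated.

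The pou5f3 transcript was lower in the MZ channel on 25 of the 29 arrays. In WT it stood at 16.53 ± 0.19 (log2 signal, SD, n = 3) at 2.5 hpf and 17.10 ± 0.08 at 8 hpf, and in MZ at 15.50 ± 0.04 and 14.50 ± 0.04. With the dye corrected and 28 arrays in the fit, the MZ-WT difference was -0.82 at 1 hpf (SE 0.20), -0.69 at 2.5 hpf, -0.65 at 3 hpf and -0.51 at 4 hpf. It was -0.79 at 4.7 hpf, -1.09 at 5 hpf, -2.05 at 6 hpf, -1.97 at 7 hpf and -2.25 at 8 hpf (SE 0.18). limma's adjusted p was 0.0477 at 4 hpf and 2.88e-08 at 8 hpf. Before the dye correction the ratios were -1.19 and -1.15 on the arrays of 1 hpf. They ran from -0.87 to -1.16 at 2.5 hpf and from -0.36 to -1.27 at 4 hpf. These early ratios are open to dye bias, since MZ was in Cy5 on each of the arrays. Without a dye coefficient none of the pou5f3 calls was lost. The call at 4 hpf ended without replicate 2 (-0.47) or replicate 3 (-0.30), at 1 hpf without replicate 1 (-0.81) or replicate 2 (-0.84), and at 3 hpf without replicate 2 (-0.54) or replicate 3 (-0.71). With 25 arrays, which leave out those labelled 0 hpf as well, it did not pass at 1 (-0.69), 2.5 (-0.55), 3 (-0.52) or 4 hpf (-0.37). With the deposited values it did not pass at 3 (-1.06), 4 (-0.64), 4.7 (-1.19) or 5 hpf (-0.73), where that table holds the gene on 3, 2, 1 and 2 of the 3 arrays, and it holds none at 1, 2.5, 6, 7 and 8 hpf. It did not pass with all 29 arrays as labelled at 1 (-1.56), 4 (-1.24) or 6 hpf (-0.33). With slide as a random block the calls at 3 and 4 hpf ended, and in fits to the arrays of a stage alone those at 1 and 4 hpf. The call at 4 hpf also ended with Agilent's processed signals, without background subtraction, with the mean of a gene's probes and without the pairing of MZ and WT. The probe lies on chromosome 16 from 27995572 to 27995631 (danRer2). Its place relative to the mutation is not given in the sources used here, so these ratios measure the level of a transcript and do not tell mutant from normal message.

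**Figure D1:**
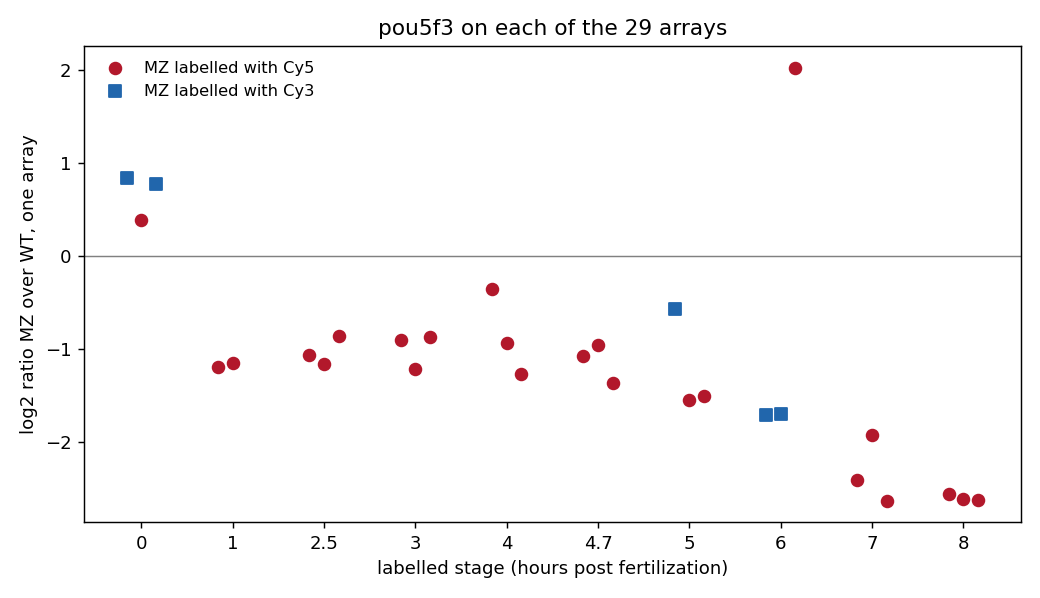
Log2 ratio of pou5f3 between MZ and WT on each of the 29 arrays, by labelled stage in hours post fertilization and by the dye of the MZ sample. The 3 arrays labelled 0 hpf and the array labelled 6 hpf replicate 3 (2.02) lie above 0, and the other 25 below.

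The array labelled 6 hpf replicate 3 went against its label. Its pou5f3 ratio was 2.02, with -1.71 and -1.69 on the other 6 hpf arrays, and its ratios correlated with theirs at r = -0.67 and -0.85 across genes, where the other pair reached r = 0.87. The 3 arrays labelled 0 hpf also had more pou5f3 in the MZ channel (0.38 to 0.83), and the fit gave 0.55 (SE 0.15, limma adjusted p = 0.0334), a call that ended without replicate 1 (0.58), replicate 2 (0.32) or replicate 3 (0.61). It also ended with 29 arrays as labelled (0.79, adjusted p = 0.446), with the mean of a gene's probes (0.49, adjusted p = 0.0637) and in a fit to the 3 arrays of this stage alone (0.59, adjusted p = 0.102). In the authors' deposited table, MZ at 0 hpf stood at 14.54 ± 0.52 (log2, SD, n = 3) and WT at 14.87 ± 0.57. These libraries also carried transcripts found at later stages. Of 120 genes that were not above background in any of the 10 channels at 1 and 2.5 hpf and were above it in WT at 4.7 hpf, 114 were above background in all 6 samples labelled 0 hpf. The organizer and notochord gene noto stood at 13.94 ± 0.15 (log2, SD, n = 3) in the library labelled WT 0 hpf and at 7.02 ± 0.10 at 2.5 hpf. The deposited table lists it at 2.80 and 2.48. The gene vox, a ventral repressor, stood at 15.02 ± 0.52 in the library labelled MZ 0 hpf in the scanner files and at 5.20 ± 1.71 in the deposited table. Across 13597 probes the scanner ratios of the 3 arrays labelled 0 hpf correlated with the deposited ratios of the same samples at r between -0.04 and 0.07, and those of the other 26 arrays at r between 0.72 and 0.99. The table columns of 3 hpf replicates 2 and 3 matched the scanner files of each other (r = 0.93 and 0.94). All values at 0 hpf therefore belong to the libraries labelled 0 hpf, and come from the scanner files where the deposited table is not named.

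**Figure D2:**
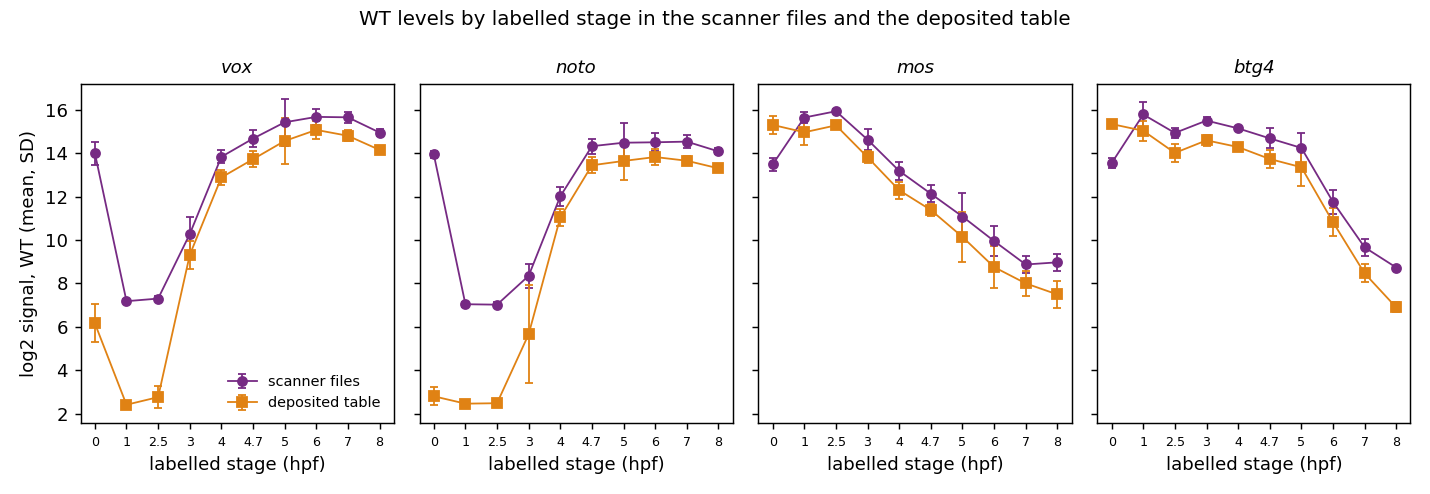
Log2 signal of vox, noto, mos and btg4 in WT at each labelled stage in hours post fertilization, from the scanner files and from the deposited table (mean, bars SD, n = 3, or 2 at 1 hpf and for vox at 8 hpf in the table). At 0 hpf noto stands at 13.94 in the scanner files and 2.80 in the table, and at 8 hpf at 14.08 and 13.30.

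In WT, the transcript of vox rose and that of the oocyte kinase gene mos fell after 2.5 hpf, and no gene list was tested between stages. At 4 hpf vox was at least 92.6-fold and mxtx2, a regulator of the yolk syncytial layer, at least 67-fold higher than at 2.5 hpf. The gene mos fell by 2.75 on the log2 scale (SE 0.37, n = 3 arrays per stage), whereas the oocyte gene btg4 stood at 14.93 ± 0.24 (log2 signal, SD, n = 3) at 2.5 hpf and 15.14 ± 0.04 at 4 hpf, and the egg coat gene zp3b at 13.56 ± 0.40 and 14.33 ± 0.61. By 8 hpf the epidermal keratin genes krt5 and krt4 had risen by 9.34 (SE 0.55) and 8.97 (SE 0.45), the caudal-type homeobox gene cdx4 by 8.47 (SE 0.27) and polr3gla at least 352-fold. Over the same time mos fell (-6.96), as did the tight junction genes cldnd (-6.26) and cldng (-6.10) and btg4 (at least 73.6-fold). In MZ, vox and mxtx2 rose as well by 4 hpf, at least 111-fold and at least 72.5-fold, and irx7 by 5.50 (SE 0.27). By 8 hpf the MZ embryos had gained the lipoprotein genes apoeb (9.40, SE 0.80) and apoc1 (at least 452-fold), the small heat shock gene hspb1 (8.78) and krt4 (8.64), and had lost btg4 (-6.54), lipg (-6.48), mos (-6.16), cldng (-5.77) and the germ line gene dazl (-5.78, SE 0.56). The highest of limma's adjusted p for these genes was 1.34e-05, that of mos at 4 hpf. In WT, 2983 genes differed at 4 hpf (922 higher, 2061 lower; 3174 with 28 arrays) and 8413 at 8 hpf (3577 higher, 4836 lower; 8484 with 28 arrays). In MZ, 2952 differed at 4 hpf (3122 with 28 arrays) and 9019 at 8 hpf (4096 higher, 4923 lower). With slide as a random block the 4 hpf counts were 677 in WT and 419 in MZ. The MZ count was 1683 without 4 hpf replicate 1 and 1932 without 2.5 hpf replicate 2. The pou5f3 transcript did not pass at 4 hpf in WT (-0.12, SE 0.13, adjusted p = 0.558) or MZ (0.05, SE 0.16), though with quantile normalization it was lower in WT (-0.51, adjusted p = 0.0319). At 8 hpf it stood 0.57 higher in WT (SE 0.13, adjusted p = 0.000751) and lower in MZ (-0.999, SE 0.162, adjusted p = 1.41e-05). The WT value did not pass with 29 arrays (adjusted p = 0.0777) or with quantile normalization (0.16, adjusted p = 0.423).

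Between the libraries labelled 0 hpf and those of 2.5 hpf, 5315 genes differed in WT and 5557 in MZ (5289 and 5415 with 28 arrays; 2646 and 3115 with slide as a random block). In the library labelled WT 0 hpf, noto was at least 112-fold, vox at least 105-fold, the mesoderm gene tbxta at least 60.3-fold and the adhesion gene alcamb at least 41.4-fold higher than at 2.5 hpf, and gstm.1 was lower (-6.07, SE 0.38). In the library labelled MZ 0 hpf, hspb1 was 8.78 higher (SE 0.80), apoeb 8.22 and vox at least 204-fold, and lpcat4 was lower (-7.64). With the deposited values the noto call ended (0.78) and those of the other genes stayed, at smaller sizes. The deposited table lists tbxta in WT at 5.48 ± 0.38 (log2, SD, n = 3) at 0 hpf and 2.46 ± 0.13 at 2.5 hpf, where the scanner files gave 13.01 ± 0.46 and 7.06 ± 0.05. The largest changes in the deposited values were those of aoc2 (8.01, SE 0.43) and slc38a4 (7.81), higher at 0 hpf in WT, and of crabp1a (-7.51, SE 1.15) and asic1b (-6.59), lower. Of 12582 genes tested in both sources in WT, 4964 were called from the deposited values and 5278 from the scanner signals, 2283 of them in both with 1 sign and 292 with opposite signs. The pou5f3 transcript was lower in WT (-0.80, SE 0.16) and did not pass in MZ (0.44, SE 0.20, adjusted p = 0.0816). In MZ it did pass, as higher at 0 hpf, with quantile normalization (0.57), without a dye coefficient (0.76), with array weights (0.55), with 58 channels in 1 fit (0.53) and with 29 arrays (0.95). Between MZ and WT at 0 hpf, 346 genes differed (519 with 28 arrays, 534 with slide as a random block, 216, 190 and 103 without replicate 1, 2 and 3). The count was 835 with quantile normalization, 1054 with Agilent's processed signals, 1162 without background subtraction and 0 in a fit to the 3 arrays of this stage alone. The lariat debranching gene dbr1 was lower in MZ (-2.86, SE 0.26), but was not called in that last fit (-2.81, adjusted p = 0.104) or from the deposited values (-0.05). Those gave 217 genes in a comparison of 12625, 7 of them shared with 1 sign and 4 with opposite signs, and in them gbgt1l4 was higher in MZ by 3.32 (SE 0.64, adjusted p = 0.00946).

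At 4 hpf, in the late blastula, several transcription factor genes were lower in the MZ embryos. Transcripts of klf17, a Krüppel-like zinc finger gene of the blastula, were 18.3-fold lower in MZ than in WT (log2 -4.19, SE 0.39, n = 3 arrays). The hairy-related repressor gene her3 was also lower (-4.09, SE 0.46). cdx4 (-2.29, SE 0.42), the forkhead gene foxi1 (3.08-fold), foxd3 (at least 2.6-fold) and mych (-1.19, SE 0.23) were lower as well. Among the genes outside the lists that were furthest below WT were the palmitoyltransferase gene zdhhc16a (-4.92), dcaf13 (-4.81), the extracellular sulfatase gene sulf2a (-4.50) and creb3l3l (-3.93). Each of these was lower in MZ at an earlier stage as well, creb3l3l at 1 hpf, zdhhc16a at 2.5 hpf, and dcaf13 and sulf2a at 3 hpf. They are thus not differences that first arose at 4 hpf. Higher in MZ were gbgt1l4 (8.84-fold, and higher at 1 and 3 hpf as well), the collectin gene colec11 (at least 5.59-fold), stmn2a (at least 5.27-fold), txnipa (2.66, SE 0.51) and cyp2v1 (2.58), whose probes were called in both directions. The BMP antagonist genes nog1 (2.09, SE 0.37) and bambia (2.05, SE 0.40), the homeobox gene hhex (at least 2.49-fold), the immediate early genes jun (1.61, SE 0.32) and atf3 (2.34-fold) were also higher. So were the neuronal RNA-binding protein gene elavl3 (at least 2.07-fold) and the embryonic globin gene hbae1.1 (at least 2.76-fold). The tubulin gene tubb5 (-1.61) and the mitotic kinase gene plk1 (-0.77) fell. limma called 3038 genes (1899 higher, 1139 lower) and 2401 with 28 arrays (1535 higher, 866 lower; 554 and 267 of them by at least 2-fold), and 1993 with 25 arrays. With 6 hpf replicate 3 kept in the fit, the count was 601 with slide as a random block, 1493 without background subtraction and 1319 without replicate 1. It was 94 in a fit to the 3 arrays of this stage alone. Of 32 genes named at 4 hpf, 24 lost their call in that last fit, foxd3, mych and foxi1 among them. The call of foxd3 also ended without background subtraction (adjusted p = 0.0864), with the mean of a gene's probes (0.088) and without the pairing of MZ and WT (0.0553). Those of mych (0.0599) and bambia (0.126) ended without the pairing, and those of krt91, elavl3 and sp5l without background subtraction. With the mean of a gene's probes krt91 and rps12 did not pass. With the deposited values cyp2v1, nog1, tubb5, plk1, atf3, rps15a and rps12 did not pass, nor did sox32 with slide as a random block. After removal of the WT time course between the apparent ages of the 2 channels, 7 of the 32 no longer passed: hhex (0.90), foxa3 (0.77), sox32 (0.81), krt91 (0.88), cpeb1b (-0.56), plk1 (-0.37) and pou5f3, which went from -0.51 to -0.57.

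Of 7 lists called at 4 hpf with 28 arrays (6 with 29), 5 were higher and 2 lower in MZ. Endoderm genes had 6 of 11 members higher and 0 lower (8 higher adjusted over the list alone; camera adjusted p = 0.00269, and adjusted p = 0.683 with an estimated correlation). Among them were foxa3 (1.90, SE 0.42) and sox32, which specifies endoderm (1.87, SE 0.54). Without replicate 1, whose MZ channel lay nearest to 5.3 hours of the WT course and its WT channel to 4.3 hours, these values were 1.23 (adjusted p = 0.0515) and 1.02 (adjusted p = 0.23), and neither passed. Dorsal organizer genes had 5 of 17 higher and 0 lower (7 adjusted over the list alone; adjusted p = 0.00611, and adjusted p = 0.683 with an estimated correlation). Nodal and mesendoderm genes had 4 of 17 and 0 (7 adjusted over the list alone; adjusted p = 0.0368, and adjusted p = 0.692 with an estimated correlation). Yolk syncytial layer genes had 4 of 9 and 0 (6 adjusted over the list alone; adjusted p = 0.015, and adjusted p = 0.683 with an estimated correlation). Ribosomal protein genes had 17 of 64 higher, such as rps15a (1.03, SE 0.21) and rps12 (1.103, SE 0.244), and 0 lower (19 adjusted over the list alone; adjusted p = 1.65e-05, and adjusted p = 0.747 with an estimated correlation). Blastula transcription factors had 5 of 9 lower and 0 higher (5 adjusted over the list alone; adjusted p = 0.00117, and adjusted p = 0.604 with an estimated correlation). Maternal and oocyte genes had 3 of 20 lower and 0 higher, among them the translation regulator gene cpeb1b (-1.13, SE 0.27; 3 adjusted over the list alone; adjusted p = 0.00496, and adjusted p = 0.604 with an estimated correlation). Without replicate 1, 2 lists were called.

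Of the lists that camera did not call at 4 hpf, heat shock and stress genes (median log2 ratio 0.363, fry adjusted p = 0.00216) and ovarian somatic and blood markers (0.463, fry adjusted p = 0.0018) were higher by fry, which tests whether the genes of a list move 1 way and does not compare them with other genes. Retinoic acid genes had a median of 0.409 and a fry adjusted p of 0.159. Ventral and BMP genes had 4 of 17 higher, bambia among them, and 2 lower, cdx4 and foxi1 (5 and 2 adjusted over the list alone; camera adjusted p = 0.219). WNT genes had 4 of 21 higher and 2 lower, cdx4 and the Wnt target gene sp5l (-1.10, SE 0.26; adjusted p = 0.847). FGF genes had 3 of 11 higher (adjusted p = 0.305). Enveloping layer genes had 3 of 11 higher, with krt91 at least 1.9-fold, and 1 lower (adjusted p = 0.203). Neural patterning genes had 3 of 26 higher. Neuronal differentiation genes had 3 of 14 higher and 1 lower. Cell cycle genes had 2 of 20 higher and 1 lower. Cell movement and adhesion genes had 3 of 19 higher and 1 lower. Heat shock and stress genes had 2 of 12 higher (jun and atf3). Housekeeping genes had 2 of 13 higher. Ovarian somatic and blood markers had 1 of 5 higher (hbae1.1). The miR-430 processing and zygotic clearance genes had 1 of 7 higher. No member of the SoxB1 factors (5 measured), the retinoic acid genes (7) or the p53 response and cell death genes (13) was called by limma. The sox2 probe was not above background in WT on any of the 3 arrays. Over all lists not called, camera's adjusted p lay between 0.186 and 0.954. Adjusted over the list alone, the counts higher and lower were 5 and 1 for FGF genes, 4 and 1 for enveloping layer genes, 3 and 2 for neuronal differentiation genes and 2 and 0 for ovarian somatic and blood markers, and as above for the others. The median and the test differed in sign for neural patterning and neuronal differentiation genes, and the mean and the test for p53 response, cell movement and housekeeping genes.

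**Figure D3:**
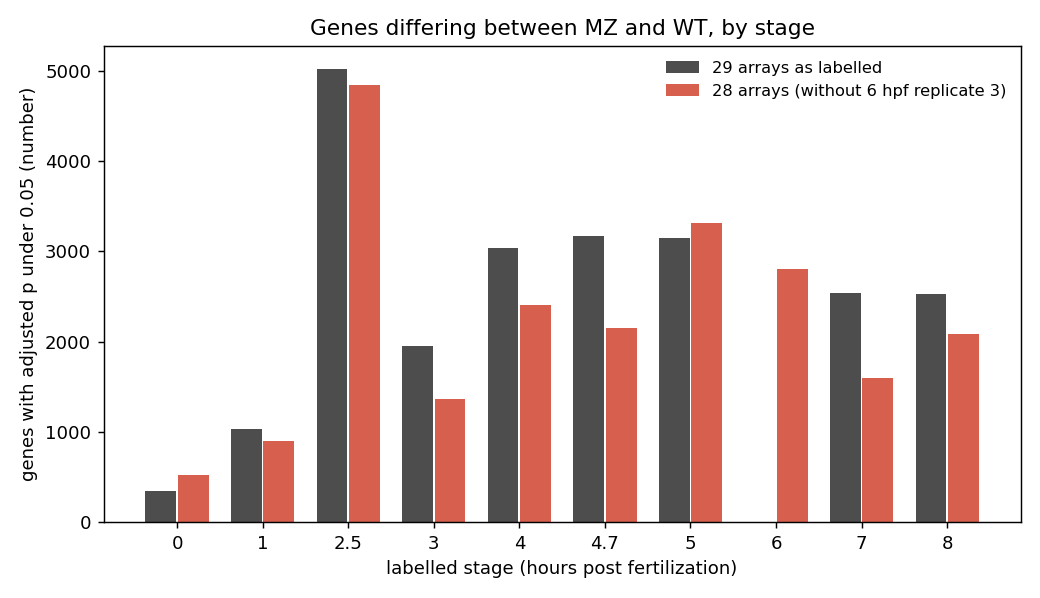
Number of genes with an adjusted p under 0.05 between MZ and WT at each labelled stage in hours post fertilization, with all 29 arrays as labelled and with the 28 arrays without 6 hpf replicate 3. At 6 hpf the count is 0 with 29 arrays and 2809 with 28, and the highest counts are those of 2.5 hpf (5023 and 4840). The array left out also shifts the dye coefficient, and with it the 29-array counts at the other stages.

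At 6 hpf, as gastrulation begins, several developmental regulators were far lower in the libraries labelled MZ of replicates 1 and 2. The SoxB1 gene sox2 of the neural plate was 60.4-fold lower (log2 -5.92, SE 0.64, n = 2 arrays) and the signalling gene bmp4 at least 44.4-fold. The gene cdx4 was also lower, and is given no fold, since its probe was well above background in MZ on 1 of 2 arrays. The gene sp5l was lower 25.5-fold (-4.67, SE 0.30) and the RNA polymerase III subunit gene polr3gla 84.8-fold (-6.41, SE 0.51). The ventral homeobox gene eve1 (-2.90, SE 0.28), the presomitic mesoderm gene msgn1 (-2.62, SE 0.37), klf17 (-4.06), mych (-2.06), her3 (at least 11.6-fold) and the organizer gene lhx1a (-1.58) were lower too. So were krt5 (-4.87, SE 0.78), the annexin genes anxa3b (-4.50) and anxa1b (at least 7.76-fold), tagln2 (at least 15.5-fold), the chemokine receptor gene cxcr4b (-2.11), the transferrin gene tfa (-1.83), the carbonic anhydrase gene cahz (-1.91, SE 0.34) and the germ line helicase gene ddx4 (-1.29). The fitted log2 values of her3 (-3.47) and anxa1b (-2.93) were smaller in size than their bounds, which take no dye coefficient. Higher were the catalase gene cat (9.15-fold, 3.19 with SE 0.65), the metalloproteinase gene mmp9 (2.78, SE 0.55), slc44a4 (2.67), klhl18 (2.53), her5 of the midbrain-hindbrain boundary (2.14, SE 0.34), lmo4b (1.40), the oocyte genes mos (1.87, SE 0.34) and cldnd (2.14), and the mitotic cyclin genes ccnb1 (1.81) and ccnb2 (1.90, SE 0.24). With all 29 arrays as labelled limma called 0 genes, 1494 had an unadjusted p under 0.05, and none of the genes named here passed. With array weights the 29 arrays gave 4334. With 28 arrays it called 2809 (1437 higher, 1372 lower; 706 and 735 of them by at least 2-fold), with the dyes of replicate 3 exchanged 2896, and with 25 arrays 2011. The deposited values of all 29 arrays gave 4 genes, and 23 were called without replicate 2 and with replicate 3 kept. In both arrays left, MZ was in Cy3, so the dye rests on other stages here, and without a dye coefficient the 28 arrays gave 3854 genes. Of 36 genes named at 6 hpf, 15 no longer passed after removal of the WT time course between the apparent ages of the 2 channels. These were eve1 (-0.58), msgn1 (-0.40), lhx1a (-0.42), tfa (-0.16), cahz (-0.46), tcf7l1a (-0.48), fgf24 (-0.80), sox3 (-0.98), etv4 (-1.01), anxa1b (-1.36), axin1 (0.91), mos (1.07), klhl18 (1.46), cxcr4b (-1.75) and cat (2.49). Of the genes that still passed, sox2 (-2.99), sp5l (-2.09) and polr3gla (-4.95) were left with smaller sizes, whereas klf17 (-3.67) and mych (-1.98) changed less. With the deposited values msgn1 (adjusted p = 0.0747) and tfa (0.249) did not pass, without the pairing her5 (0.0721) and tcf7l1a (0.153), and with 25 arrays axin1 (0.0506).

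With 28 arrays, 5 of the lists were called at 6 hpf, all lower in MZ (3 with 29 arrays). Blastula transcription factors had 8 of 9 members lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 1.65e-05, and adjusted p = 0.533 with an estimated correlation). Ventral and BMP genes had 5 of 17 lower, bmp4, cdx4 and eve1 among them (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.00269, and adjusted p = 0.683 with an estimated correlation). WNT genes had 7 of 21 lower, with the repressor gene tcf7l1a at -0.97 (SE 0.18), and 1 higher, axin1 (1.49, SE 0.36), whose call ended without replicate 2 (value 1.204; 9 and 2 adjusted over the list alone; adjusted p = 0.00726, and adjusted p = 0.683 with an estimated correlation). FGF genes had 5 of 11 lower, such as fgf24 (at least 3.05-fold) and the FGF target gene etv4 (-1.83, SE 0.32; 5 adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.604 with an estimated correlation). Enveloping layer genes had 6 of 11 lower, led by krt5 and anxa1b (6 adjusted over the list alone; adjusted p = 0.00219, and adjusted p = 0.604 with an estimated correlation). Without replicate 1 or replicate 2, and with replicate 3 kept, 1 list was called. The SoxB1 factors (sox2 and sox3 lower of 5; adjusted p = 0.0643) and the Nodal and mesendoderm genes (5 of 17 lower, 2 higher; adjusted p = 0.0548) missed the threshold. The gene sox3 stood at -1.79 (SE 0.46), a call that ended without replicate 1 (-1.42) and with the deposited values (-0.94). Retinoic acid genes had 4 of 7 lower, the receptor gene raraa (at least 3.4-fold) among them, and 1 higher. Dorsal organizer genes had 3 of 17 lower and 1 higher. Cell movement and adhesion genes had 5 of 19 lower. Yolk syncytial layer genes had 2 of 9 lower and 1 higher. Endoderm genes had 1 of 11 lower. Ovarian somatic and blood markers had 1 of 5 lower (cahz). Maternal and oocyte genes had 6 of 20 higher and 1 lower. Cell cycle genes had 4 of 20 higher and 3 lower. Heat shock and stress genes had 6 of 12 higher. Ribosomal protein genes had 3 of 64 higher and 2 lower. Neural patterning genes had 3 of 26 each way. Neuronal differentiation genes had 2 of 14 higher and 1 lower. The p53 response genes had 1 of 13 higher and 2 lower. The miR-430 processing and zygotic clearance genes had 2 of 7 higher and 1 lower. Housekeeping genes had 1 of 13 higher. Adjusted over the list alone, the counts higher and lower were 1 and 5 for dorsal organizer, 2 and 8 for Nodal and mesendoderm, 7 and 2 for maternal and oocyte, 0 and 0 for ribosomal protein, and 3 and 1 for miR-430 processing and zygotic clearance genes, 2 and 1 for ovarian somatic and blood markers, and as above for the others. Over the lists not called, camera's adjusted p lay between 0.0548 and 0.908. The median and the test differed in sign for neural patterning and neuronal differentiation genes.

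At 8 hpf, in mid gastrulation, neural patterning genes were among those far lower in MZ. The gene her3 was 44.9-fold lower than in WT (log2 -5.49, SE 0.46, n = 3 arrays), sox2 34.9-fold (-5.13, SE 0.56), the head homeobox gene otx1 16.2-fold (-4.02, SE 0.29), the hindbrain gene hoxb1b 10.4-fold (-3.38, SE 0.34) and zic1 9.16-fold (-3.20, SE 0.23). Lower as well were polr3gla (-5.27, SE 0.44), spag7 (-6.47), the glucose transporter gene slc2a12 (-5.36), gpd1b (-4.71, SE 0.29), scinlb (-4.38) and tmem208 (at least 15.2-fold). The same held for the Krüppel-like genes klf2a (-2.74, SE 0.38) and klf2b (-2.07), foxd3 (4.42-fold), the epidermal genes foxi1 (-2.13, SE 0.25), gata2a (-2.40, SE 0.48) and tp63 (-1.51, SE 0.32), and the Nodal co-receptor gene tdgf1 (-2.73, SE 0.29). Higher in MZ were hel_dr5 (at least 14.7-fold), the growth factor gene pdgfaa (at least 13.4-fold), the T-box gene tbx2a (at least 12.9-fold), the forebrain gene vax1 (at least 8.38-fold), and gbx2 of the midbrain-hindbrain region (at least 7.88-fold). The fitted log2 values of pdgfaa (3.50) and tbx2a (3.42) were smaller than these bounds, which take no dye coefficient. Further genes higher in MZ were pax6a (at least 5.03-fold), the Notch ligand gene dlb (at least 5.64-fold), the histone gene h2ax (3.54, SE 0.64), fkbp1ab (3.60, SE 0.59), her2 (3.15) and cat (3.25, SE 0.57). The Nodal ligand gene ndr1 (1.53, SE 0.25), its mediator gene foxh1 (0.99, SE 0.21), the chemokine genes cxcl12a (1.79, SE 0.33) and cxcl12b (0.74), and snai1a (1.08, SE 0.16) rose. limma called 2529 genes (1342 higher, 1187 lower) and 2088 with 28 arrays (1093 higher, 995 lower; 433 and 400 of them by at least 2-fold), and 1621 with 25 arrays. With 6 hpf replicate 3 kept in the fit, the count was 842 with slide as a random block, 1636 without replicate 2 and 1365 without replicate 3. It was 4007 from Agilent's processed signals, with that array kept as well, and 5063 in a fit to the 3 arrays of this stage alone. The call of cxcl12b ended with Agilent's processed signals (adjusted p = 0.202), with the deposited values (0.0854) and without the pairing of MZ and WT (0.0751). That of dhrs3b ended with the processed signals (0.0572) and with 25 arrays (0.0513), and those of rrm1, mcm5 and sfrp1a with the deposited values. After removal of the WT time course between the apparent ages, 3 of 52 genes named at 8 hpf no longer passed: tp63 (-0.58), ndr1 (0.89) and dla (-0.43). Of those that still passed, hoxb1b (-1.67) and zic1 (-2.13) were left with smaller sizes, whereas her3 (-5.45) and sox2 (-5.52) changed less.

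Of 3 lists called at 8 hpf with 28 arrays (4 with 29), blastula transcription factors had 6 of 9 members lower and 0 higher (6 adjusted over the list alone; camera adjusted p = 1.65e-05, and adjusted p = 0.533 with an estimated correlation). Neural patterning genes had 8 of 26 lower, zic1, otx1 and hoxb1b among them, and 2 higher, pax6a and gbx2 (9 and 2 adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.68 with an estimated correlation). Ribosomal protein genes had 8 of 64 higher and 0 lower (8 adjusted over the list alone; adjusted p = 0.0249, and adjusted p = 0.869 with an estimated correlation). Without replicate 1, 2 lists were called. Neuronal differentiation genes went both ways, with 4 of 14 higher, dlb and lmo4b (1.37, SE 0.22) among them, and 4 lower, such as dla (-0.88, SE 0.11). Of the 7 retinoic acid genes, the binding protein gene crabp2a was higher, with its probe well above background in WT on 1 of 3 arrays, and raraa (-3.03, SE 0.32), dhrs3b (-1.53, SE 0.36) and the degrading enzyme gene cyp26a1 (-2.09, SE 0.27) were lower (camera adjusted p = 0.831). FGF genes had fgf17 higher (1.82, SE 0.47) and fgf24 lower (-1.75, SE 0.24) of 11. Ventral and BMP genes had 2 of 17 higher and 3 lower. Dorsal organizer genes had 4 of 17 higher. Nodal and mesendoderm genes had 3 of 17 higher and 1 lower. Endoderm genes had 1 of 11 lower, sox17, whose probe was well above background in MZ on 2 of 3 arrays. Yolk syncytial layer genes had 2 of 9 higher. Enveloping layer genes had 3 of 11 lower, with anxa1b at -2.35 (SE 0.42). SoxB1 factors had 1 of 5 lower (sox2). WNT genes had 2 of 21 higher and 3 lower, such as sfrp1a (-1.41, SE 0.26). Cell movement and adhesion genes had 5 of 19 higher and 2 lower. Cell cycle genes had 1 of 20 higher and 4 lower, with mcm5 at -1.06 (SE 0.20) and rrm1 at -0.98 (SE 0.14). Heat shock and stress genes had 2 of 12 each way, with jun at 1.55 (SE 0.32). Maternal and oocyte genes had 2 of 20 higher. The p53 response and cell death genes had 1 of 13 higher. Housekeeping genes had 2 of 13 higher, with actb1 at 1.03 (SE 0.17). Ovarian somatic and blood markers had 2 of 5 higher, hbae1.1 (at least 2.25-fold) and cyp17a1 (1.48, SE 0.34). None of the 7 miR-430 processing and zygotic clearance genes was called by limma. Adjusted over the list alone, the counts higher and lower were 5 and 3 for ventral and BMP, 4 and 3 for retinoic acid, 1 and 0 for maternal and oocyte, 0 and 0 for p53 response, and 5 and 3 for cell movement and adhesion genes, and as above for the others. Over the lists not called, camera's adjusted p lay between 0.0528 and 0.934. The median and the test differed in sign for Nodal, retinoic acid and cell cycle genes, and the mean and the test for neuronal differentiation genes.

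**Figure D4:**
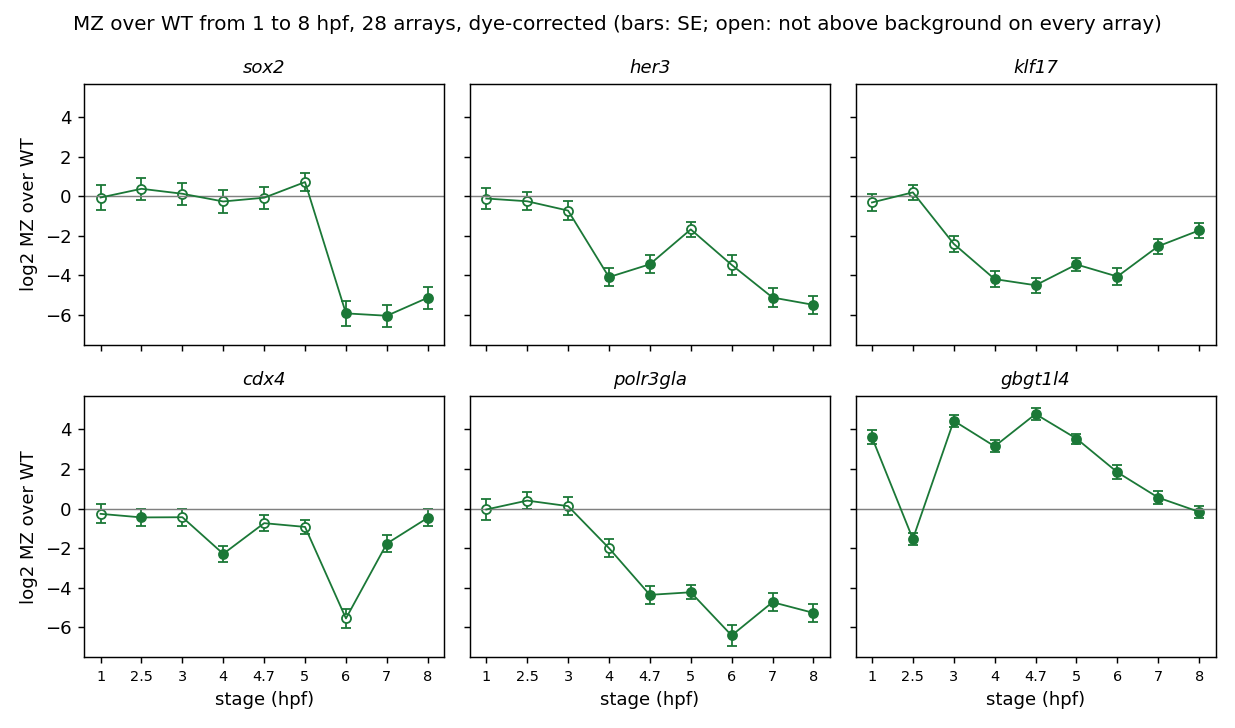
Log2 ratio of MZ over WT (bars SE, 28 arrays) for sox2, her3, klf17, cdx4, polr3gla and gbgt1l4 from 1 to 8 hours post fertilization, 6 genes chosen after their values were seen. Open circles mark stages where the probe was not well above background in MZ and WT on every array, and their values give no size. klf17 stands at -4.19 at 4 hpf and sox2 at -5.92 at 6 hpf, and gbgt1l4 lies above 0 at all these stages except 2.5 (-1.54) and 8 hpf.

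At the remaining stages the sets of differing genes differed widely in size. At 1 hpf, before zygotic transcription, slc39a13 (5.31, SE 1.06) and gbgt1l4 (3.59, SE 0.35) were higher in MZ, and rab6a (-6.31, SE 1.15) and creb3l3l (-3.96, SE 0.40) were lower. There limma called 1037 genes (896 with 28 arrays, 590 with 25, 527 with slide as a random block, 379 without replicate 1 and 436 without replicate 2, n = 2 arrays). The count was 2081 with quantile normalization, 2343 with Agilent's processed signals, 2001 without background subtraction and 1740 with the deposited values. In a fit to the 2 arrays of this stage alone it was 0, and the 4 genes named here lost their call (adjusted p = 0.188). The most genes differed at 2.5 hpf, 5023 (4840 with 28 arrays, 2349 with slide as a random block), where the MZ channels lay nearest to 3.1 hours of the WT course and the WT channels to 2.4 to 2.6 hours. More genes were called at 8 hpf than at 2.5 hpf with quantile normalization (3590 and 3492) and with Agilent's processed signals (4007 and 3863). At 2.5 hpf mrpl43 was at least 35.1-fold and dusp14 26.5-fold higher in MZ, and spag7 at least 136-fold, zdhhc16a at least 87.7-fold and rab6a (-8.22, SE 1.00) lower. At 3 hpf gbgt1l4 (4.43, SE 0.31) and slc44a4 (3.28) were higher and sulf2a (-5.61, SE 0.50) and dcaf13 (-5.42) lower. The count at 3 hpf was 1950 (1362 with 28 arrays, 949 with 25, 785 with slide as a random block, 695 without replicate 3). At 4.7 hpf gbgt1l4 (4.77, SE 0.31) and mrpl43 (at least 15.7-fold) were higher and dcaf13 (-5.03) lower. The count at 4.7 hpf was 3175 (2154 with 28 arrays, 1593 with 25, 540 with slide as a random block, 1783 and 1728 without replicates 1 and 2). At 5 hpf gbgt1l4 (3.53, SE 0.25) was higher and polr3gla (-4.23, SE 0.36) lower. The count at 5 hpf was 3147 (3311 with 28 arrays, 1489 with slide as a random block, 1300 without replicate 2), and it was lower still in a fit to the 3 arrays of this stage alone, as given below. At 7 hpf cyp2v1 (11.8-fold) was higher and sox2 (-6.04, SE 0.56), her3 (-5.12) and polr3gla (-4.73) lower. The count at 7 hpf was 2538 (1597 with 28 arrays, 1125 with 25, 1002 with slide as a random block, 991 and 1078 without replicates 1 and 2). A fit to the 3 arrays of 7 hpf alone called 68 genes. In it the values of sox2, her3 and polr3gla were -5.95, -5.05 and -4.67, with adjusted p between 0.062 and 0.0734.

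At later stages the MZ-WT difference itself departed from that at 2.5 hpf for many genes, and for fewer when 3 hpf was the reference. Against 2.5 hpf, gbgt1l4 shifted toward MZ by 4.69 at 4 hpf (SE 0.35) and 6.31 at 4.7 hpf, rab6a by 5.17 (SE 1.13), 6.25 and, at 8 hpf, 6.73, and the histone gene h2ax by 4.31 at 4 hpf and 5.51 at 8 hpf (SE 0.72). The shift of gbgt1l4 rests on its value at 2.5 hpf (-1.54), since it was higher in MZ at 1 hpf (3.59) and 3 hpf (4.43) as well. In the other direction went gpd1b (-6.00, SE 0.33) and slc2a12 (-5.44) at 8 hpf. The same call was made for klf17 at 4 and 4.7 hpf, her3 at 4 hpf, pygmb at 4.7 hpf, polr3gla at 4.7 and 8 hpf and sox2 at 8 hpf. These are given no size, since their probes were not well above background at 2.5 hpf in WT on every array, and for her3 and polr3gla on none in MZ either. limma called 3762 genes at 4 hpf, 4278 at 4.7 hpf and 4412 at 8 hpf (4384, 4856 and 5014 with 28 arrays; 1216, 1747 and 1973 with slide as a random block). Measured against 3 hpf in place of 2.5 hpf, the counts with 28 arrays were 116, 334 and 2583. Most calls at 4 and 4.7 hpf thus rest on the values of 2.5 hpf. The 2.5 hpf arrays shared a slide with 1 hpf replicate 1, whose ratios correlated with theirs at r of 0.708, 0.625 and 0.656. Replicate 2 of 1 hpf, on another slide, reached 0.336, 0.369 and 0.332. Whether the slide is the cause stays open. The counts against 2.5 hpf were also lower with quantile normalization at 4 hpf and with the deposited values at 4 and 4.7 hpf, as given below. The pou5f3 difference changed by 0.18 at 4 hpf (SE 0.20, adjusted p = 0.521) and by -0.11 at 4.7 hpf (adjusted p = 0.71), neither of which passed. With quantile normalization the change at 4 hpf did (0.70, adjusted p = 0.0117). At 8 hpf it changed by -1.57 (SE 0.20, adjusted p = 4.84e-06).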

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

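The splits and the age tests at 4, 6 and 8 hpf were planned, and the age test at 2.5 hpf and the counts with 28 arrays and against 3 hpf were chosen after the result was seen. The MZ-WT difference departed from that at 2.5 hpf for 3762 genes at 4 hpf, 4278 at 4.7 hpf and 4412 at 8 hpf, by limma's test of the difference itself. Against 3 hpf with 28 arrays these counts were 116, 334 and 2583. The pou5f3 difference changed by -1.565 on the log2 scale between 2.5 and 8 hpf (SE 0.199, adjusted p = 4.84e-06), with MZ lower on 3 of 3 arrays at both stages.

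MZ and WT channels of an array lay up to 1 hour apart on the WT time course, and at the same point on 5 hpf replicates 1 and 3. At 2.5 hpf the MZ channel lay 0.5 to 0.7 hours ahead on all 3 arrays. At 4 hpf it lay 1 hour ahead on replicate 1 (5.3 against 4.3 hours), 0.3 ahead on replicate 2 and 0.3 behind on replicate 3. At 6 hpf the 2 MZ channels of replicates 1 and 2 lay at 5.5 and 5.6 hours and the WT channels at 6.1 and 5.9. If a difference in developmental age were the cause, removing the WT time course between the apparent ages would leave under 50% of the calls. At 2.5 hpf, against which the later stages were compared, 33.1% of the 4840 genes stayed called with their sign (median size 0.85 before and 0.48 after, median SE 0.20 and 0.22). At 4 hpf 37.8% of the 2401 genes stayed called with their sign (median size 0.81 before and 0.64 after, median SE 0.21 and 0.22) and at 6 hpf 21.1% of 2809 (1.02 and 0.64, SE 0.24 and 0.27). Some of these calls ended through a smaller effect and some through a wider error. The ages were fitted to these same channels, so the removal tends to shrink differences whatever their cause. A low share at these 3 stages therefore cannot tell age from other causes, and age stays open there. At 4 hpf the median size after removal was 79.2% of that before, and 2392 of the 2401 genes kept their sign. At 8 hpf 58.7% of 2088 stayed (0.87 and 0.76), which argues against age as the whole cause, and at the stages from 1 to 7 hpf not named here between 54.7% and 71.9%. Of the genes named in the text, 25 of 32 kept their call at 4 hpf, 21 of 36 at 6 hpf and 49 of 52 at 8 hpf. Kept were klf17 (-3.74) and her3 (-3.61) at 4 hpf, sox2 at 6 hpf, from -5.92 (SE 0.64) to -2.99 (SE 0.79), and her3 (-5.45) and sox2 (-5.52) at 8 hpf. At 4 hpf hhex (0.90), foxa3 (0.77), sox32 (0.81), krt91 (0.88), cpeb1b (-0.56), plk1 (-0.37) and pou5f3 no longer passed, the last with a value that went from -0.51 to -0.57. At 6 hpf this held for eve1 (-0.58), msgn1 (-0.40), lhx1a (-0.42), tfa (-0.16), cahz (-0.46), tcf7l1a (-0.48), fgf24 (-0.80), sox3 (-0.98), etv4 (-1.01), anxa1b (-1.36), axin1 (0.91), mos (1.07), klhl18 (1.46), cxcr4b (-1.75) and cat (2.49), and at 8 hpf for tp63 (-0.58), ndr1 (0.89) and dla (-0.43). Of these, krt91 went from 1.19 to 0.88, cxcr4b from -2.11 to -1.75 and cat from 3.19 to 2.49, so most of their size stayed and the loss of the call does not point to age. Smaller parts stayed for axin1 (from 1.49), klhl18 (from 2.53) and mos (from 1.87). A delay caused by the loss of Pou5f3 itself was not tested and stays open.

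The 6 samples of a comparison can be parted into groups of 3 in 10 ways, too few for a share under 0.05. For MZ against WT only 4 of the 10, the real one included, part MZ from WT on every array. Each of the others rests on the MZ-WT ratio of 1 array, and each array enters 2 of them. Those are real comparisons of a single array, not groupings by chance. For MZ against WT the real split was the only 1 of the 10 with as many genes at 0 hpf (346, the highest other 149), 2.5 hpf (5023 and 161), 3 hpf (1950 and 87), 4 hpf (3038 and 1800), 4.7 hpf (3175 and 31), 5 hpf (3147 and 544), 7 hpf (2538 and 206) and 8 hpf (2529 and 7). The 1800 of 4 hpf came from replicate 1 alone. Among the 4 splits that part every array, the highest others were 1 at 0 hpf, 19 at 2.5 hpf, 5 at 3 hpf and 18 at 4 hpf. They were 18 at 4.7 hpf, 25 at 5 hpf, 206 at 7 hpf and 3 at 8 hpf. At 6 hpf, where limma called 0 genes as labelled and 1494 had an unadjusted p under 0.05, all 10 splits gave as many, and the split that exchanges MZ and WT on replicate 3 gave 2896, which points to a structure of these samples. For the changes against 2.5 hpf it was again 1 of 10, with 4, 45 and 0 as the highest others at 4, 4.7 and 8 hpf. For 0, 4 and 8 hpf against 2.5 hpf the highest others were 1, 1 and 0 in WT (5315, 2983 and 8413 in the real split) and 0, 0 and 0 in MZ (5557, 2952 and 9019). For gene lists, 5 of the 10 splits gave at least the 6 lists of 4 hpf (highest other 9), 7 at least the 3 of 6 hpf (8) and 2 at least the 4 of 8 hpf (4). These tallies include the splits that rest on 1 array. Among the 4 that part every array, the highest others were 9, 5 and 4.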

How the results depend on the processing

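The alternatives with 28 or 25 arrays, with the dyes of 6 hpf replicate 3 exchanged, without dye in 28 arrays and against 3 hpf were chosen after the result was seen. Counts without the filter on dim probes and with the mean of a gene's probes stayed within 1.5 times in 19 of 19 cases each. Of 3742 values of named genes (207 results, 123 genes), 3597 kept their direction and side of the threshold, 137 lost the call, 7 gained it and 1 reversed, pou5f3 at 0 hpf with the authors' deposited values (-0.347), and 123 results changed under none of their alternatives. The genes were named chiefly because they kept their call when any single array was left out. The share that kept its call is therefore partly set by that choice and does not hold for all called genes. With the 29 arrays as labelled 40 of 207 lost the call, with the arrays of a stage alone 34 of 169 and with the deposited values 20 of 182. Signal over background limits the values of dim genes, since between 35.4% and 69.7% of the probes stood well above it. For the counts below the cause was not tested, except that fits to fewer arrays have fewer degrees of freedom.

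For MZ against WT, quantile normalization gave 835 genes at 0 hpf, 2081 at 1 hpf and 5 at 6 hpf, 2322 for the change at 4 hpf against 2.5 hpf, and 6 lists at 6 hpf. Agilent's processed signals gave 1054 (0 hpf), 2343 (1 hpf) and 4007 (8 hpf), and no background subtraction 1162 (0 hpf), 2001 (1 hpf), 1493 (4 hpf) and 11 (6 hpf). The share of calls that were higher in MZ at 0 hpf moved from 37.3% to 52.8% with the processed signals and 47.5% without background subtraction, and that of the change at 4.7 hpf from 61.1% to 49.9% with the deposited values. The deposited values gave 217 (0 hpf), 1740 (1 hpf), 1424 (4 hpf), 1623 (4.7 hpf) and 4 (6 hpf), and 1949 and 2566 for the changes at 4 and 4.7 hpf. With the replicate number as a replicate block, the count at 4 against 2.5 hpf in WT was 3054, and the others between stages were 5282 (0 hpf) and 8497 (8 hpf) in WT and 5519, 3014 and 9032 in MZ. The block changed none of the calls of the 38 gene results named there. At 4 hpf in WT 2 of the 3 samples correlated best with the 2.5 hpf sample of their own number. With slide as a random block there were 534 (0 hpf), 527 (1 hpf), 2349 (2.5 hpf), 785 (3 hpf), 601 (4 hpf), 540 (4.7 hpf), 1489 (5 hpf), 1002 (7 hpf) and 842 (8 hpf). The changes at 4, 4.7 and 8 hpf numbered 1216, 1747 and 1973. Against 2.5 hpf there were 2646 at 0 hpf and 677 at 4 hpf in WT and 3115 and 419 in MZ. Array weights gave 652 (0 hpf), 4334 (6 hpf), and for 4 against 2.5 hpf 6490 in WT and 1685 in MZ. Without the block that pairs MZ and WT there were 202 genes at 0 hpf and 11 lists at 6 hpf, and without a dye coefficient 1 list at 6 hpf.

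The arrays of a stage alone gave 0 genes by limma at 0 hpf (4317 with an unadjusted p under 0.05) and 0 at 1 hpf (2246), 1018 at 3 hpf, 94 at 4 hpf, 956 at 5 hpf, 68 at 7 hpf, 5063 at 8 hpf and 6632 for the change at 8 hpf. With 28 arrays there were 2809 genes at 6 hpf and 1597 at 7 hpf and 5 lists at 6 hpf, and with the dyes exchanged 2896, 1536 and 5. With 25 arrays the counts were 590 (1 hpf), 949 (3 hpf), 1993 (4 hpf), 1593 (4.7 hpf), 2011 (6 hpf), 1125 (7 hpf) and 1621 (8 hpf), and with 28 arrays and no dye 520 (0 hpf), 2948 (3 hpf) and 3854 (6 hpf). Against 3 hpf the changes numbered 116, 334 and 2583. Camera with an estimated correlation called 0 lists at 4 hpf (0 with an unadjusted p under 0.05), 0 at 6 hpf (0) and 0 at 8 hpf (1), and fry 3, 0 and 2 (10, 1 and 8 unadjusted), all with 29 arrays as labelled. With 28 arrays fry called 8, 9 and 4 (10, 12 and 5 unadjusted).

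With 1 array left out in turn, the counts ran from 103 to 216 at 0 hpf, 379 to 436 at 1 hpf, 3794 to 4135 at 2.5 hpf, 695 to 1830 at 3 hpf, 1319 to 2961 at 4 hpf, and 1728 to 2520 at 4.7 hpf. They ran from 1300 to 2313 at 5 hpf, 0 to 2809 at 6 hpf, 991 to 3191 at 7 hpf and 1365 to 1883 at 8 hpf. The lowest came without replicate 3 at 0 hpf, replicate 1 at 1 hpf, replicate 3 at 3 hpf, replicate 1 at 4 hpf, replicate 2 at 4.7 and 5 hpf, replicate 1 at 6 hpf and 7 hpf, and replicate 3 at 8 hpf. The changes ran from 2660 to 3511 at 4 hpf, 3282 to 3806 at 4.7 hpf and 3304 to 3835 at 8 hpf. Against 2.5 hpf they ran in WT from 4440 to 4985 at 0 hpf, 2258 to 2566 at 4 hpf and 7811 to 8048 at 8 hpf, and in MZ from 4059 to 5237, 1683 to 3126 and 8438 to 8578. Lists ran from 2 to 7 at 4 hpf, 1 to 5 at 6 hpf and 2 to 3 at 8 hpf.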

Other observations

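All tests on the samples labelled 0 hpf, and those of a dye bias, of exchanged samples and of a failed hybridisation on 6 hpf replicate 3, were chosen after the result was seen, and 2 of them, the dye test and the test of pou5f3 loss at 0 hpf, were changed after a first value of theirs was seen, whereas the age test was planned. Apart from the array labelled 6 hpf replicate 3, 21 genes differed by over 1.5-fold with 1 sign on all 25 arrays from 1 to 8 hpf, 10 higher and 11 lower in MZ, a set chosen after its values were seen. Lower were aldh2.2 (median log2 ratio -4.39), selenot1a (-2.46), hsd3b2 (-2.29) and scamp1 (-1.78), and higher were cdk5 (2.16), brox (2.04) and invs (1.80). Neighbouring stages shared calls: with 28 arrays 736 genes were called with 1 sign at both 3 and 4 hpf and 3 with opposite signs, 1128 and 2 at 4 and 4.7 hpf, 1207 and 13 at 4.7 and 5 hpf, 1190 and 38 at 5 and 6 hpf, 661 and 30 at 6 and 7 hpf, and 823 and 9 at 7 and 8 hpf. Earlier, 617 and 11 were shared by 1 and 2.5 hpf and 734 and 64 by 2.5 and 3 hpf, whereas 0 and 1 hpf shared 27 with 1 sign and 88 with opposite signs. A dye bias common to all stages would give opposite signs at 6 hpf, where MZ was in Cy3 on both arrays left, and at 7 hpf, where it was in Cy5. Without a dye coefficient, 10.3% of 1441 genes called at both had opposite signs, which argues against such a bias as the whole cause of these shared calls. Between stages that both had MZ in Cy5 on every array it was not tested and stays open.

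The array labelled 6 hpf replicate 3 ran against the others. Of the 21 genes above, 100% had the opposite sign on it, such as aldh2.2 (4.89) and cdk5 (-1.77), which is consistent with MZ and WT having been exchanged on this array, in the dye labels or in the tubes. A failed hybridisation would leave its ratios unrelated to those of the other 6 hpf arrays, and the correlation across genes nearer to 0 was -0.667. Another developmental age would put a channel outside the range of the other 6 hpf channels, and both lay 0 hours outside it. Which step exchanged the samples, if any, was not tested, and no biological explanation was tested.

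The 6 samples labelled 0 hpf carried transcripts that were not above background at 1 and 2.5 hpf. RNA of eggs or ovary would lack most of 120 such genes, and 95% were above background in all 6 samples, against 0.833% in all 6 samples of 3 hpf, which argues against it for the scanner files. The apparent ages were 4.9 to 5.2 hours, and 6 of 6 samples lay nearest to a point from 4 to 8 hpf, consistent with RNA of embryos past the start of zygotic transcription. Yet klf17 stood at 8.46 in the library labelled WT 0 hpf (13.73 in WT at 4.7 hpf), her3 at 7.65 (10.27) and foxd3 at 7.67 (9.99), each less than 1 above WT at 2.5 hpf (7.53, 7.56 and 7.02). As a hypothesis, all 6 samples, those labelled WT included, could be of embryos without pou5f3. Values of other genes in the library labelled MZ 0 hpf go against it. There krt4 stood at 15.06, where MZ had 10.83 at 4.7 hpf and 12.96 ± 0.44 (SD, n = 3) at 5 hpf. The pou5f3 transcript itself stood at 16.26 there, where MZ had 15.47 at 4.7 hpf and 15.28 ± 0.44 at 5 hpf. In the library labelled WT 0 hpf krt4 stood at 13.30. This is above MZ at 4.7 hpf but within the SD of MZ at 5 hpf, so it does not decide. Of 822 genes that differed at 4.7 hpf, at least 73.1% in each of the 6 lay nearer to the MZ than to the WT level. In WT at 5 hpf, near the apparent age of these libraries, the share was 7.42% to 34.7%, and at 8 hpf it was 54.6% to 56.2%. No WT sample of another stage from 1 to 8 hpf reached 73.1%, that of the array labelled 6 hpf replicate 3 included. For these 822 genes this argues against age along the WT course as the whole cause of the share. The genotype stays open, since krt4 and pou5f3 in the library labelled MZ 0 hpf go against the hypothesis. The highest correlation across probes between the ratios of these 3 arrays and the deposited ratios of the same samples was 0.067, where the lowest of the other 26 arrays was 0.724, which suggests that the scanner files are of other arrays than those behind the deposited table. Where the arrays came from was not tested, and no biological explanation was tested.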
